A study of Homo sapiens with 12 samples.

How the data were processed

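RNA from HK-2 cells, a line of immortalised epithelial cells from the human renal proximal tubule, was measured on 12 Affymetrix arrays. The cells had been exposed to a high dose of a compound that the labels call Aa, or to its vehicle, for 24 h or 48 h. Each of the 4 groups held 3 samples that the labels call biological replicates. The dose and the identity of Aa are not given in the sources used here, and neither are scan dates or other batches of the arrays.

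The deposited table holds log2 expression values that the authors made with GCRMA, per the submitters' processing notes. GCRMA corrects each probe's background from its sequence, normalises between arrays and summarises the probes of a probe set. The version of GCRMA and the arrays that were normalised together are not given in the sources used here. Biotinylated cRNA was prepared by the manufacturer's protocol, per the labels' protocols. The log base was read from the values: medians lay between 2.91 and 3.02 on all arrays, the lowest mode was at 2.30, and values at equal rank differed between arrays by at most 0.309. Such a step sets the arrays to nearly the same distribution, so a change shared by most transcripts would not appear in these values. Values near the lowest mode are background, and differences among them carry no order.

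The table held 54675 probe sets, 62 of which were the manufacturer's controls. In the platform annotation 41091 of the others named 1 gene, 1801 named several and 11721 named none. Of those naming 1 gene, 41037 matched NCBI's RefSeq gene table (assembly GRCh38.p14) by Entrez number, and 0 symbols needed an update. Each of 19775 genes was represented by the probe set with the highest mean over the 12 arrays. A gene was tested if its value was over log2 4 on at least 3 of the 12 arrays, which left 11184 genes and excluded 8591. Gene spans came from the same RefSeq table, and no coordinates were used because the annotation's build is not given in the sources used here.

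Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a model of the 4 group means over all 12 arrays, with 8 residual and 2.79 prior degrees of freedom. The contrasts were Aa minus control at 24 h, Aa minus control at 48 h, the 48 h change minus the 24 h change, and control at 48 h minus control at 24 h. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and were also counted with a log2 change of at least 1 in size. Every adjusted p given for a gene is from limma. The median standard error of a gene's log2 change was 0.161 for the comparisons within a time or between controls, and 0.227 for the difference between times. The number of arrays limits this precision. Where an array of the dimmer group lay under log2 4, it entered the fold at log2 4 and the other arrays at their own values, and the fold is given as at least that size. The fitted log2 change of such a gene is no bound and carries no order.

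A total of 27 gene lists were tested, covering stress responses, the cell cycle, metabolism, inflammation, the proximal tubule and markers of other cell types. Members were counted over all genes tested and adjusted over the list alone. Lists were set against all other genes with camera at a preset correlation of 0.01, with adjustment over the 26 lists that had a tested member. Camera was repeated with an estimated correlation, and fry was run as well. Camera called 6 lists at 24 h, 7 at 48 h, 7 for the difference between times and 6 between control times. With an estimated correlation it called 0 in each, where the smallest adjusted p was 0.219, 0.248, 0.0678 and 0.255. Fry, which asks whether the genes of a list moved on balance in 1 direction without setting them against other genes, called 14, 16, 11 and 2 lists. For changes in either direction, fry called 24, 24, 23 and 10.

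Genes were named by a rule. It took the 6 largest fitted rises and falls at each time among genes with a log2 change of at least 1 and no overlap of the groups. It added up to 2 genes per list with the largest change at that time, and the 5 largest positive and 5 largest negative fitted values of the other contrasts. ACTB, GAPDH, HAVCR1, CDKN1A, MDM2 and HMOX1 were named whatever their values. The groups, the tests, the lists, this rule and the alternatives were set before the data were examined, except a scaling to the hybridisation controls, which was chosen after seeing the data, as were the symbol families, transcript classes, span classes and the set of genes near background described last. The rule's genes whose calls changed between alternatives are mostly described with those alternatives.

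The replicate numbers in the labels were checked for pairing. Deviations from the group means correlated between 0.279 and 0.577 for all 18 pairs of samples with the same number in different groups, and between -0.372 and -0.0286 for the 36 pairs with different numbers. The numbers therefore paired the samples, although what same-numbered samples shared is not given in the sources used here. The model without this block was the one set beforehand. The estimated correlation of camera came from that model, so differences between replicate numbers stayed in it. Camera with the block was run only at the preset correlation. A fit with the replicate number as a block gave identical log2 changes, a smaller standard error for 10510 of the 11184 genes and fewer total degrees of freedom (8.72 in place of 10.8), and is given beside a result where it changed the call or moved a count by over 1.5 times.

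The alternatives were no filter, a stricter filter at log2 6, quantile normalisation, equal array medians, scaling to hybridisation controls, every probe set, the mean of a gene's probe sets, no probe sets with the suffixes _x_at or _s_at, a floor at log2 4, trend and robust eBayes, array weights, only the compared groups, the replicate block, an adjusted p under 0.01, and leaving out each of the 12 arrays in turn. The hybridisation controls are bacterial and phage transcripts spiked into each sample before hybridisation, and their signal also depends on the amount of labelled cRNA loaded. On average they were brighter on Aa arrays by 0.28 at 24 h and 0.44 at 48 h on the log2 scale, and brighter on 48 h than on 24 h control arrays by 0.32. Setting them equal moved the median log2 change of all genes from 0.02 to -0.26 at 24 h, from -0.03 to -0.47 at 48 h, from -0.07 to -0.23 for the difference between times and from -0.01 to -0.32 between control times. Changes are therefore relative to the median of all genes, and the size of a shift shared by all transcripts stays unknown.

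The steps were tested on simulated data with the real genes' means and spread, with 11184 genes. At 24 h 17.9% of 67 genes with a simulated log2 change of 0.5 were called, 82.1% of 67 at 1 and 100% of 66 at 2, and 6 unchanged genes were called. Far fewer genes changed in the simulation than in the real data, and adjusted p depends on that number. The simulated noise held no replicate pairs and no correlation between genes. These shares therefore may not carry over to the real comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.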

Results

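Gene expression was measured in HK-2 cells, which retain several features of the proximal tubule and are widely used to study toxicity to the kidney. Cells received a high dose of Aa or vehicle for 24 h or 48 h, with 3 biological replicates in each of the 4 groups, as part of a search for expression signatures of toxicity. Arrays of the same group correlated at 0.994 to 0.997 over all probe sets, and Aa arrays correlated with control arrays at 0.949 to 0.975. The first principal component held 78.1% of the variance and separated the 6 Aa arrays from the 6 control arrays. The second component held 7.96% and separated Aa at 24 h from Aa at 48 h, with the control arrays between them. The difference between 3' and 5' control probe sets, a measure of RNA quality, averaged over ACTB and GAPDH 0.394 on Aa arrays and 0.306 on control arrays at 24 h, and 0.542 and 0.319 at 48 h (log2). The reference transcripts ACTB and GAPDH did not pass the test at 24 h, with log2 changes of -0.09 (adjusted p = 0.586) and 0.03 (adjusted p = 0.782); the GAPDH value fell below 0 with equal array medians and with hybridisation-control scaling. At 48 h ACTB changed by -0.29 (adjusted p = 0.0634, and 0.00623 with the replicate block). GAPDH changed by -0.08 (adjusted p = 0.423), with the sign turned by quantile normalisation.

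The first comparison asked which transcripts differed between Aa and vehicle at 24 h. Transcripts of the stress regulator ATF3, the growth arrest genes CDKN1A and GADD45A, and the hormone gene STC2 were higher in Aa-treated cells, while 14 of 18 cholesterol synthesis genes and 17 of 31 mitosis genes were lower. ATF3 rose from log2 5.00 ± 0.47 to 10.30 ± 0.17 (SD, n = 3), a 39.4-fold rise, although 1 of its 3 probe sets went the other way. CDKN1A, which encodes an inhibitor of cyclin-dependent kinases, rose 3.08-fold (log2 change 1.62, SE 0.216, adjusted p = 0.000113). In all, 5492 of 11184 genes changed (49.1%), 2942 upward and 2550 downward, and 2310 of them had a fitted change of at least 2-fold (1218 up, 1092 down). With hybridisation-control scaling the split was 1668 up and 3860 down, or 30.2% up in place of 53.6%.

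Of the 6 genes named for their fitted rises, 5 were near background in control cells, so their order is unknown. CEL, which encodes a bile salt-dependent lipase, rose at least 32.3-fold, LSMEM1 at least 48.3-fold, the amine oxidase gene AOC3 at least 38.1-fold, the lactase gene LCT at least 24-fold and CFAP251 at least 23.2-fold. GCNA, a gene of germ cells, rose 73-fold, from log2 5.22 ± 0.65 to 11.41 ± 0.25. One of the 3 probe sets of CFAP251 went the other way. Genes named for their fitted falls were SYT1 (at least 42.8-fold lower), the exocyst gene EXOC4 (at least 33.4-fold), the receptor phosphatase gene PTPRG (at least 29.7-fold), the scaffold gene GPHN (at least 21.5-fold) and the formin gene DIAPH2 (at least 17.3-fold). SCEL, which encodes sciellin of epithelial cell envelopes, was also among them and 44.4-fold lower, with no array of 24 h under log2 4. Adjusted p for these 12 genes ranged from 7.47e-10 (AOC3) to 0.000458 (SCEL).

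Among mitosis genes 17 of 31 fell at 24 h and the other 14 did not pass (19 fell when adjusted over the list alone). DLGAP5, a spindle protein gene, fell by 1.66 (SE 0.114) and the kinetochore motor gene CENPE fell by 1.52 (SE 0.105) on the log2 scale. The list median was -0.54 (camera adjusted p = 2.5e-05; adjusted p = 0.556 with an estimated correlation). Of 31 DNA replication genes 12 rose and 5 fell, the same counts as adjusted over the list alone. The replication factor genes MCM10 and CDT1 rose 2.37-fold and 2.24-fold. The list median of 0.18 (camera adjusted p = 0.421) turned to -0.10 with hybridisation-control scaling. Of 8 tested histone genes 6 rose, also when adjusted over the list alone, among them H2AC6 by 2.33 (SE 0.296). The histone median of 1.26, or 0.95 with a floor at log2 4, passed camera (adjusted p = 0.0387), but not with an estimated correlation (adjusted p = 0.556) or with the replicate block (adjusted p = 0.0739).

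Of 29 p53 targets 13 rose and 6 fell, also over the list alone. SERTAD1 rose by 2.17 (SE 0.329) and GADD45A by 1.85 (SE 0.168). MDM2, which encodes the ligase that degrades p53, had a log2 change of 0.22 (adjusted p = 0.226), with 5 of its 10 probe sets in that direction, and -0.07 with hybridisation-control scaling. The p53 list median was 0.22 (camera adjusted p = 0.296) and -0.06 with that scaling. In the DNA repair and checkpoint list 12 of 24 genes rose and 2 fell, over all genes and over the list alone, among them the nuclease gene ERCC4 with a rise of 2.20 (SE 0.264). Its median was 0.41 (camera adjusted p = 0.0527, and 0.0461 with the replicate block; adjusted p = 0.556 with an estimated correlation).

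Of 23 NRF2 targets, a set of antioxidant genes, 13 rose and 1 fell (14 and 2 when adjusted over the list alone). OSGIN1 was at least 4.02-fold higher and HMOX1, which encodes heme oxygenase 1, was 2.02-fold higher (adjusted p = 0.00184). The list median was 0.36 (camera adjusted p = 0.0255; adjusted p = 0.219 with an estimated correlation). Of 25 genes of ATF4 and amino acid stress 14 rose and 2 fell, also over the list alone. STC2, which encodes stanniocalcin 2, rose 10.2-fold (log2 change 3.35, SE 0.279). The list median was 0.50 (camera adjusted p = 0.0255; adjusted p = 0.556 with an estimated correlation). Of 18 cholesterol synthesis genes 14 fell and 4 did not pass, and over the list alone 15 fell and 1 rose. The sterol reductase gene TM7SF2 fell by 2.02 (SE 0.362) and HMGCS1, which encodes the synthase of an early step, fell by 1.64 (SE 0.164). The list median was -0.65 (camera adjusted p = 0.000314; adjusted p = 0.219 with an estimated correlation).

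Interferon response genes rose at 24 h in 13 of 22 cases and fell in 1, also over the list alone. The antiviral gene MX1 was at least 1.92-fold higher and IFIT2 was 2.86-fold higher. The list median was 0.75 (camera adjusted p = 0.0255; adjusted p = 0.637 with an estimated correlation). Of 17 genes of NF-kB and cytokines 8 rose and 3 fell, with a median of 0.41, or 0.25 with a floor at log2 4 (camera adjusted p = 0.391); IL6 rose by 2.88 (SE 0.812, adjusted p = 0.0124) and IRF1 by 2.10 (SE 0.158). Of 17 immediate early genes 8 rose and 2 fell (median 0.46, camera adjusted p = 0.314). JUN rose by 1.65 and EGR1 fell by 1.79. These counts were the same over either list alone.

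Of 29 listed proximal tubule genes 25 were on the array, and only 8 were over the expression filter and tested. Among these 8 genes 4 fell and 4 did not pass, with the same count over the list alone. SLC3A1, which encodes a subunit of the cystine transporter, fell by 1.96 (SE 0.442). The list median was -0.83 (camera adjusted p = 0.0527, and 0.0216 with the replicate block; adjusted p = 0.565 with an estimated correlation). Of 19 kidney injury markers 2 rose and 5 fell (median -0.15, camera adjusted p = 0.314), also over the list alone. HAVCR1, which encodes kidney injury molecule 1, was lower by 2.08-fold (log2 change -1.06, SE 0.111, adjusted p = 2.18e-05). The keratin gene KRT20 was at least 6.07-fold lower, with 2 of 3 Aa arrays under log2 4, and the growth factor gene HBEGF rose 7.59-fold by the probe set used, while 2 of its 4 probe sets went the other way.

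In the other lists fewer genes moved or members went both ways at 24 h. Hypoxia and glycolysis genes had 7 risen and 3 fallen of 20 (camera adjusted p = 0.631), led by ALDOC (at least 15.3-fold higher) and ADM (4.26-fold higher), and their median of 0.04 turned negative with equal array medians and hybridisation-control scaling. Ribosome biogenesis genes had 4 risen and 2 fallen of 19 (4 and 0 over the list alone by limma, 5 and 3 at an unadjusted p under 0.05; camera adjusted p = 0.459), with NOP2 up 2.67-fold, and a median of 0.21 that turned negative with hybridisation-control scaling. Aryl hydrocarbon receptor targets had 4 risen and 1 fallen of 6 (camera adjusted p = 0.314), with AHRR at least 2.45-fold and CYP1B1 3.53-fold higher. Matrix and TGF-beta targets had 2 risen and 6 fallen of 19 (2 and 5 over the list alone; camera adjusted p = 0.391), and TAGLN rose 2.74-fold. Apoptosis genes had 2 risen and 5 fallen of 16 (camera adjusted p = 0.631), and BCL2, which encodes an inhibitor of apoptosis, had a log2 change of -1.90 (SE 0.554). Lysosome and autophagy genes had 5 risen and 5 fallen of 20 (camera adjusted p = 0.937), with MCOLN1 up 3.07-fold and UVRAG changed by -2.38. The medians of the apoptosis and lysosome lists were 0.03 and 0.03, and turned negative with equal array medians and hybridisation-control scaling.

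Oxidative phosphorylation genes had 4 fallen of 24 at 24 h (2 over the list alone; median -0.03, camera adjusted p = 0.421), ER chaperones 1 risen and 3 fallen of 19 (1 and 0 over the list alone by limma, 2 and 5 at an unadjusted p under 0.05; median -0.11, camera adjusted p = 0.49) and metallothioneins 2 fallen of 8 (0 over the list alone by limma, 4 at an unadjusted p under 0.05; median -0.29, camera adjusted p = 0.327). Heat shock genes had 1 risen and 3 fallen of 13 (1 and 2 over the list alone; camera adjusted p = 0.873), with a median of 0.05 that turned negative with equal array medians and hybridisation-control scaling. Among markers of other cell types, 4 of the distal nephron and podocyte genes were tested at 24 h, with 1 risen and 1 fallen (camera adjusted p = 1). By limma 0 of 2 fibroblast and 0 of 3 endothelial markers passed, with 1 fibroblast marker lower and 1 endothelial marker higher at an unadjusted p under 0.05 (camera adjusted p = 0.444 and 0.832). Of 10 leukocyte markers 0 passed the expression filter. The median, mean and test differed in sign for the heat shock, apoptosis, lysosome and distal nephron lists, none of which passed camera. Except where given, counts over the lists alone were the same.

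**Figure D1:**
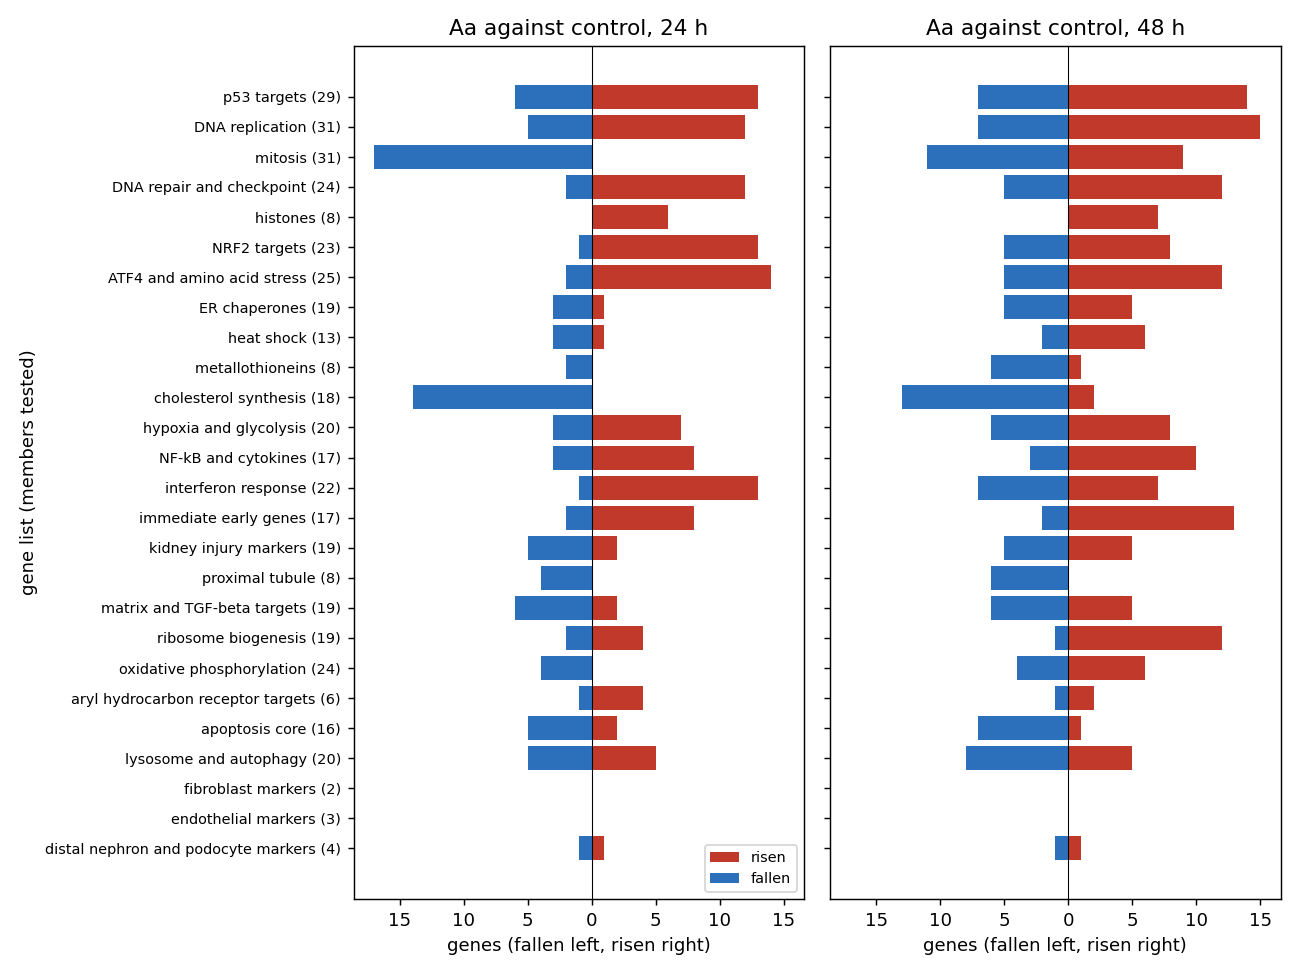
Horizontal bars give the number of genes per list that rose (red, to the right) or fell (blue, to the left) with Aa at 24 h and at 48 h, with the members tested in parentheses. At 24 h 17 of 31 mitosis genes fell, and at 48 h 9 rose and 11 fell.

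The second comparison asked the same at 48 h. In Aa-treated cells 7 of 8 histone genes, 13 of 17 immediate early genes and 12 of 19 ribosome biogenesis genes were higher, and 6 of 8 proximal tubule genes and 13 of 18 cholesterol synthesis genes were lower. ATF3 rose 117-fold, from log2 5.35 ± 0.70 to 12.22 ± 0.33 (SD, n = 3). IL11, which encodes a cytokine, rose at least 29.2-fold, from 2.64 ± 0.25 to 8.87 ± 0.39. In all, 7210 of 11184 genes changed (64.5%), 3423 upward and 3787 downward, and 3572 had a fitted change of at least 2-fold (1635 up, 1937 down). With hybridisation-control scaling 1808 rose and 5889 fell, or 23.5% up in place of 47.5%.

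Genes named for their fitted rises at 48 h, in no order, were LSMEM1 (at least 69.5-fold), AOC3 (at least 76.9-fold), SHISA2 (at least 93.3-fold), CEL (at least 43.9-fold), ATF3 and the glycogen phosphorylase gene PYGM (at least 28.4-fold). The kidney injury marker HBEGF, which was not among them, rose 56.8-fold from control values over log2 4. Genes named for their fitted falls were the orphan receptor gene GPR160 (at least 43.3-fold lower), SYT1 (at least 42.7-fold), GPHN (at least 38.1-fold), the membrane adaptor gene ANK3 (at least 41.9-fold), the kinase gene PRKCB (at least 31.5-fold) and PTPRG (at least 41.3-fold). For GPR160, SYT1, ANK3 and PTPRG 2 of 3 Aa arrays lay under log2 4. One of 5 probe sets of ANK3 and 1 of 6 of PRKCB went the other way. Adjusted p for these 12 genes ranged from 1.41e-10 (AOC3) to 9.38e-05 (ANK3).

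Of 8 histone genes 7 rose at 48 h, also over the list alone, with a median of 3.56, or 2.98 with a floor at log2 4 (camera adjusted p = 0.000649; adjusted p = 0.248 with an estimated correlation). H2BC4 was at least 14.6-fold and H3C2 at least 9.24-fold higher. Of 31 DNA replication genes 15 rose and 7 fell, led by MCM10 (4.77-fold) and CDC6 (3.65-fold), both of which act at replication origins. From 24 h to 48 h MCM10 went from log2 8.665 to 7.488 in control cells and from 9.911 to 9.741 in Aa cells. CDC6 went from 9.666 to 8.678 in control cells and from 10.57 to 10.54 in Aa cells. The list median of 0.28 (camera adjusted p = 0.233) turned to -0.16 with hybridisation-control scaling. Of 31 mitosis genes 9 rose and 11 fell (median -0.16, camera adjusted p = 0.874). The kinase gene AURKB rose 2.51-fold and the proliferation marker MKI67 2.23-fold, the latter in 3 of its 4 probe sets. In the DNA repair list 12 of 24 rose and 5 fell (camera adjusted p = 0.233), with the nuclease gene EXO1 up 4.39-fold and the ligase gene RAD18 up 3.73-fold, in 3 of its 4 probe sets. Between the times EXO1 went from log2 8.912 to 8.006 in control cells and from 10.24 to 10.14 in Aa cells. The repair median of 0.24 turned to -0.20 with hybridisation-control scaling. Counts over these lists alone were the same.

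Of 17 immediate early genes 13 rose and 2 fell at 48 h, with a median of 1.26 (camera adjusted p = 0.00255; adjusted p = 0.607 with an estimated correlation). FOS, a subunit of the AP-1 transcription factor, rose 18.3-fold and FOSB at least 11.1-fold. Of 17 genes of NF-kB and cytokines 10 rose and 3 fell, with a median of 1.05 (camera adjusted p = 0.0339; adjusted p = 0.607 with an estimated correlation). IL6 rose at least 24.5-fold, with 1 of 3 control arrays under log2 4 (log2 change 5.20, SE 0.812, adjusted p = 2e-04). Of 22 interferon response genes 7 rose and 7 fell (camera adjusted p = 0.718), with OAS3 up 5.16-fold and IFI44L at least 16.4-fold lower, with 1 of 3 Aa arrays under log2 4, and the median of 0.14 turned to -0.30 with hybridisation-control scaling. Counts over these 3 lists alone were the same.

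Ribosome biogenesis genes rose in 12 of 19 cases and fell in 1 at 48 h, also over the list alone, with NOP2 up 4.60-fold and the RNA polymerase subunit gene POLR1C up 2.91-fold. The median was 0.57 (camera adjusted p = 0.0254; adjusted p = 0.607 with an estimated correlation). Of 18 cholesterol synthesis genes 13 fell and 2 rose (14 and 2 over the list alone). INSIG1, a sterol-responsive regulator, was lower by 5.22-fold and TM7SF2 by 9.36-fold. The median was -0.67 (camera adjusted p = 0.0254; adjusted p = 0.607 with an estimated correlation). Of 8 metallothionein genes 6 fell and 1 rose, also over the list alone. MT1F was lower by 2.23-fold and MT1G by 2.26-fold, with 1 of 2 probe sets of MT1G going the other way. The median of -1.0 passed camera (adjusted p = 0.0469), but not with an estimated correlation (adjusted p = 0.607) or the replicate block (adjusted p = 0.0848).

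Of the 8 proximal tubule genes over the expression filter, from 25 on the array, 6 fell at 48 h and 2 did not pass, also over the list alone. The bicarbonate cotransporter gene SLC4A4 was lower by 8.32-fold, and SLC3A1 by 11.3-fold in the probe set used, while 2 of its 3 probe sets went the other way. The median was -1.22 (camera adjusted p = 0.0439; adjusted p = 0.607 with an estimated correlation), which did not pass camera when no expression filter was set. Of 19 kidney injury markers 5 rose and 5 fell (median -0.09, camera adjusted p = 0.874), also over the list alone. KRT20 was at least 25-fold lower, and HAVCR1 was lower by 2.07-fold (log2 change -1.05, SE 0.111, adjusted p = 1.16e-05).

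Of 29 p53 targets 14 rose and 7 fell at 48 h (camera adjusted p = 0.271). SERTAD1 rose 26-fold, CDKN1A rose 3.90-fold and CYFIP2 was lower by 9.42-fold. MDM2 fell by 0.54 on the log2 scale (SE 0.140, adjusted p = 0.0055) in the probe set used, with 3 of its 10 probe sets in that direction, and the mean of its probe sets, at -0.07, did not pass. Of 25 genes of ATF4 and amino acid stress 12 rose and 5 fell (camera adjusted p = 0.271), with STC2 up 11-fold. Of 23 NRF2 targets 8 rose and 5 fell (camera adjusted p = 0.455). OSGIN1 was at least 5.97-fold higher, the cystine transporter gene SLC7A11 was lower by 4.48-fold, and HMOX1 changed by -0.13 (adjusted p = 0.603). The medians of these lists, 0.32, 0.30 and 0.19, turned to -0.12, -0.14 and -0.25 with hybridisation-control scaling. Counts over each list alone were the same.

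**Figure D2:**
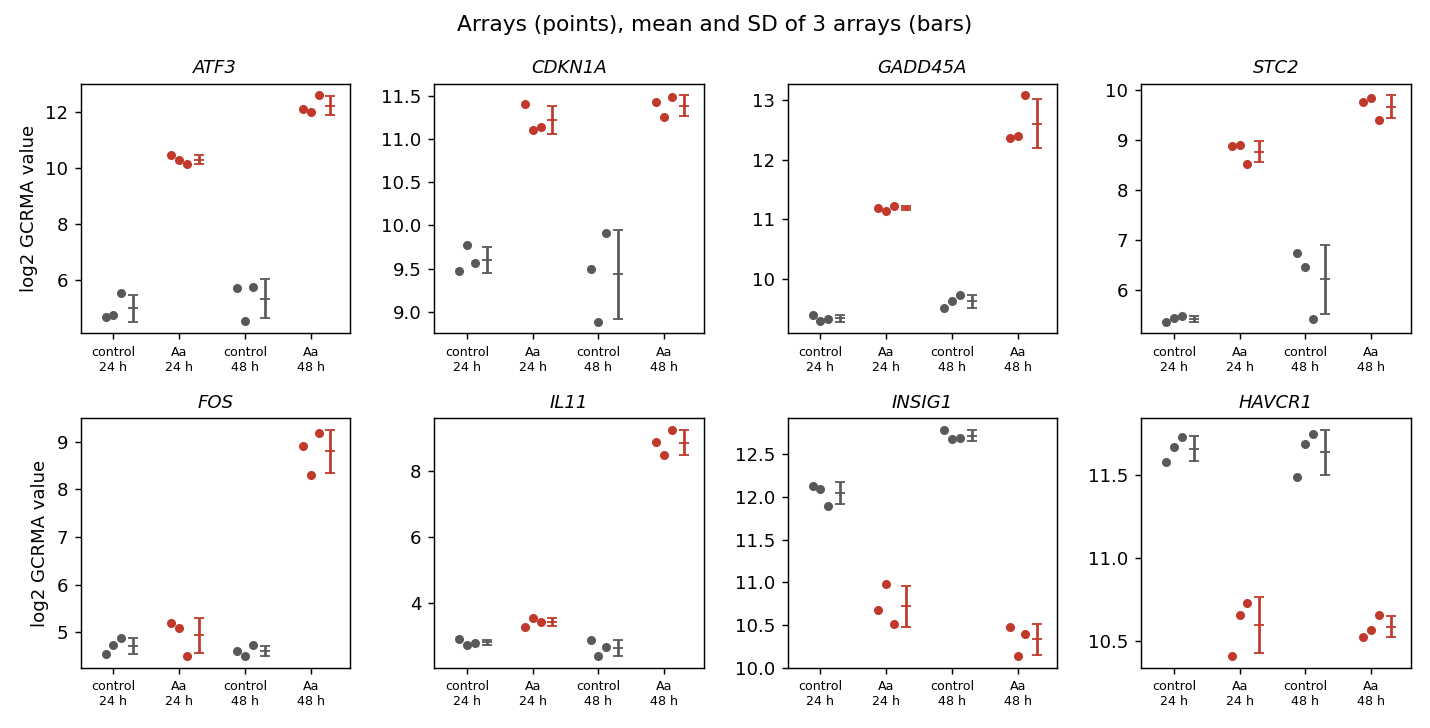
Points give the log2 GCRMA value of each array for 8 genes in the 4 groups (control in grey, Aa in red), and bars give the mean and SD of 3 arrays; vertical axes differ between panels and do not start at 0. IL11 lay at 2.64 ± 0.25 in control and 8.87 ± 0.39 with Aa at 48 h, and INSIG1 at 12.72 ± 0.06 and 10.33 ± 0.18.

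Members of the remaining lists mostly went both ways at 48 h, with no list passing camera. Hypoxia and glycolysis genes had 8 risen and 6 fallen of 20 (camera adjusted p = 0.446), with ALDOC at least 29.4-fold and ADM 30.8-fold higher. Heat shock genes had 6 risen and 2 fallen of 13 (6 and 3 over the list alone; camera adjusted p = 0.324), with the co-chaperone genes CHORDC1 up 2.49-fold and FKBP4 up 2.24-fold. Matrix and TGF-beta targets had 5 risen and 6 fallen of 19 (camera adjusted p = 0.871), with TAGLN at least 11.9-fold higher, with 2 of 3 control arrays under log2 4, and SNAI2 at least 4.07-fold higher. Aryl hydrocarbon receptor targets had 2 risen and 1 fallen of 6 (camera adjusted p = 0.874), with CYP1B1 up 2.97-fold and TIPARP lower by 7.78-fold. Oxidative phosphorylation genes had 6 risen and 4 fallen of 24 (5 and 4 over the list alone; camera adjusted p = 0.874). The medians of these 5 lists, from 0.04 to 0.20, turned negative with hybridisation-control scaling, and that of aryl hydrocarbon receptor targets also with a floor at log2 4 (-0.02).

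ER chaperone genes had 5 risen and 5 fallen of 19 at 48 h (camera adjusted p = 0.874), with DNAJB11 up 2.23-fold and XBP1 lower by 2.46-fold. Apoptosis genes had 1 risen and 7 fallen of 16 (median -0.15, camera adjusted p = 0.446). BIK, which promotes apoptosis, rose 5.73-fold, and BCL2, which inhibits it, was at least 12.2-fold lower, in 3 of its 4 probe sets and with 2 of 3 Aa arrays under log2 4. Lysosome and autophagy genes had 5 risen and 8 fallen of 20 (camera adjusted p = 0.905), with MCOLN1 up 5.57-fold and UVRAG at least 7.12-fold lower, with 1 of 3 Aa arrays under log2 4; their median of -0.02 turned positive with quantile normalisation and equal array medians. Of 4 distal nephron and podocyte markers 1 rose and 1 fell (camera adjusted p = 0.718), with a median of 0.15 that turned to -0.29 with hybridisation-control scaling. By limma 0 of 2 fibroblast and 0 of 3 endothelial markers passed, with 0 fibroblast markers and 1 endothelial marker at an unadjusted p under 0.05 (camera adjusted p = 0.874 for both lists). The median, mean and test differed in sign for ER chaperones, kidney injury markers, aryl hydrocarbon receptor targets and endothelial markers. Except where given, counts over these lists alone were the same as over all genes.

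The third comparison asked whether the response differed between 24 h and 48 h. The log2 changes of IL11, TNFAIP6, FOSB and 6 of 8 histone genes were higher at 48 h than at 24 h, as were those of 16 of 31 mitosis genes. With a floor at log2 4, the difference between the log2 changes was 4.87 for IL11 (SE 0.218, adjusted p = 9.8e-07), 4.58 for the sarcolipin gene SLN, 3.6 for TNFAIP6, a secreted hyaluronan-binding protein gene, 3.53 for ZNF143-AS1 and 3.47 for FOSB. The fitted differences without that floor were 5.62 for IL11, 4.95 for TNFAIP6, 4.71 for ZNF143-AS1 and 4.78 for FOSB, and carry no order because arrays of these 4 genes lay under log2 4. With the floor TNFAIP6 changed by -2.21 and SLN by -2.95 between the times in control cells, against 1.39 and 1.63 in Aa cells, and SLN had an SD of 1.73 among control arrays at 48 h. Negative differences with the floor were -3.11 for the B-cell linker gene BLNK (SE 0.446), whose control value changed by 3.11 between the times with the floor, -3.01 for the iron exporter gene SLC40A1 in 1 of its 2 probe sets, and -3.18 for SLC6A3. LPP at -3.21, in 4 of its 8 probe sets, and FAM13A at -2.61, in 4 of its 5, passed with all arrays but not with most single arrays left out. In all, 2179 of 11184 genes differed (19.5%), 761 toward a higher and 1418 toward a lower change at 48 h, and 4314 differed with the replicate block. With single arrays left out the count was 1241 (without control replicate 3 of 24 h) to 2597 (without control replicate 3 of 48 h). The share of positive differences was 34.9%, against 47.1% with equal array medians (937 and 1051 genes) and 17.9% with hybridisation-control scaling (339 and 1557 genes).

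Mitosis genes had 16 positive differences of 31 (20 over the list alone), with a median of 0.53 (camera adjusted p = 1.16e-09; adjusted p = 0.387 with an estimated correlation). Over these 31 genes the median change between the times was -0.53 in control cells and 0.05 in Aa cells. In the deposited values the fall in control cells was therefore about as large as the whole difference. With hybridisation-control scaling the median in Aa cells was -0.425, so this split between control and Aa cells depends on the scaling. Histone genes had 6 of 8 (median 2.31, or 2.04 with a floor at log2 4, camera adjusted p = 1.13e-06; adjusted p = 0.0678 with an estimated correlation). Immediate early genes had 8 of 17 (median 0.54, camera adjusted p = 3.35e-05; adjusted p = 0.387 with an estimated correlation). Ribosome biogenesis genes had 5 of 19 (7 positive and 1 negative over the list alone), with a median of 0.53 (camera adjusted p = 0.000719; adjusted p = 0.439 with an estimated correlation). NF-kB and cytokine genes had 4 positive and 1 negative of 17, with a median of 0.65 (camera adjusted p = 0.0128; adjusted p = 0.439 with an estimated correlation), which did not pass camera when no expression filter was set. Heat shock genes had 4 positive of 13 (median 0.25, camera adjusted p = 0.0103; adjusted p = 0.439 with an estimated correlation), with medians between the times of -0.15 in control cells and 0.13 in Aa cells. The heat shock median in Aa cells turned to -0.346 with hybridisation-control scaling. Metallothionein genes had 6 negative of 8 (median -0.71, camera adjusted p = 0.0103; adjusted p = 0.439 with an estimated correlation). The other 19 tested lists did not pass camera for this difference. Except where given, counts over the list alone were the same.

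Most genes called at both times moved in the same direction. In total 2244 genes rose at both times and 2141 fell at both, where independent lists would give 900.44 and 863.45, and 86 moved in opposite directions, where independent lists would give 1776.6. The 2 comparisons share no arrays. Across genes, which are not independent replicates, the log2 changes correlated at 0.862 (Pearson) and 0.807 (Spearman). Of the 4385 genes called in the same direction, 3011 had the larger change at 48 h (68.7%) and 1374 the smaller, as counts of fitted values without a test per gene. Of the 2179 genes with a tested difference, 964 were called at 48 h and not at 24 h, 288 at 24 h and not at 48 h, and 826 at both times in the same direction.

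**Figure D3:**
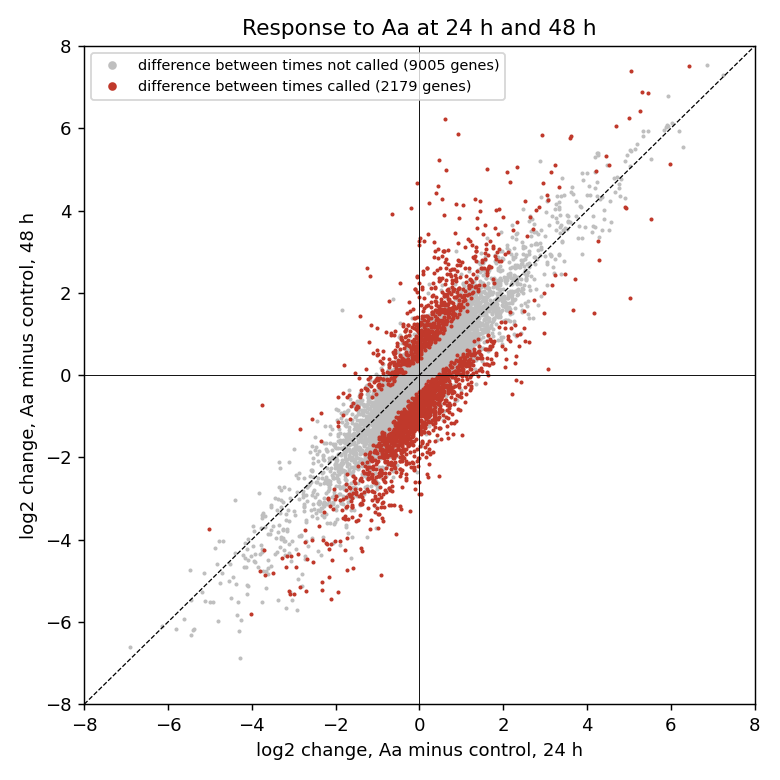
Each point is 1 of 11184 genes, with its log2 change with Aa at 24 h on the horizontal axis and at 48 h on the vertical axis. Red points are the 2179 genes whose change differed between the times, and the dashed line marks equal change.

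The fourth comparison gave the change of control cells between 24 h and 48 h. TNFAIP6 was at least 4.64-fold lower in control cells at 48 h, the collagenase gene MMP1 at least 8.63-fold lower, with 1 of 3 arrays at 48 h under log2 4, and the actin-binding protein gene TAGLN at least 6.25-fold lower, with 2 of 3. BLNK was at least 8.66-fold higher, with 2 of 3 arrays at 24 h under log2 4, COL4A3 at least 1.76-fold and KISS1R at least 1.70-fold higher at 48 h, with 5 of 7 probe sets of COL4A3 going the other way; neither COL4A3 nor KISS1R passed with a floor at log2 4. BLNK did not pass without control replicate 1 of 24 h (3.63) or without control replicate 1 (3.78) or 2 (3.63) of 48 h. In all, 71 of 11184 genes differed (0.635%), 31 upward and 40 downward, and 1669 differed with the replicate block. Fitted on the 6 control arrays alone, limma called 0 genes, with 1836 at an unadjusted p under 0.05 and a smallest adjusted p of 0.104. Leaving out single arrays gave from 9 genes (without control replicate 1 of 24 h) to 545 (without control replicate 3 of 48 h). The share of rises was 43.7%, against 66.7% with equal array medians (26 and 13 genes) and 1.65% with hybridisation-control scaling (32 and 1913 genes).

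Mitosis genes were lower in control cells at 48 h, with 4 of 31 fallen over all genes and 30 when adjusted over the list alone (median -0.53, camera adjusted p = 5.4e-23; adjusted p = 0.255 with an estimated correlation). DNA replication genes had 2 of 31 fallen, and 18 over the list alone (median -0.39, camera adjusted p = 1.14e-12; adjusted p = 0.255 with an estimated correlation). Matrix and TGF-beta targets had 3 of 19 fallen, and 5 over the list alone (median -0.07, camera adjusted p = 0.0203; adjusted p = 0.721 with an estimated correlation). ATF4 and amino acid stress genes had 1 of 25 risen, and 3 over the list alone, with a median of 0.21 (camera adjusted p = 0.00442; adjusted p = 0.674 with an estimated correlation) that turned to -0.10 with hybridisation-control scaling. By limma 0 heat shock genes passed over all genes or over the list alone, with 2 of 13 lower at an unadjusted p under 0.05 (median -0.15, camera adjusted p = 0.0268; adjusted p = 0.674 with an estimated correlation). Likewise 0 ribosome biogenesis genes passed, with 3 of 19 lower at an unadjusted p under 0.05 (median -0.13, camera adjusted p = 0.0341; adjusted p = 0.745 with an estimated correlation). By limma 0 of 8 proximal tubule genes passed, with 3 higher at an unadjusted p under 0.05. Their median of 0.31 passed camera with the replicate block (adjusted p = 0.0184) and not without the block (adjusted p = 0.105; adjusted p = 0.745 with an estimated correlation), and turned to -0.00384 with hybridisation-control scaling.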

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

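Among the tests in this part, the test of DNA replication genes beside the histones and the full set of 32 assignments were chosen only after the result was seen. The response to Aa differed between 24 h and 48 h for 2179 genes by the test of the difference itself. Of 100 assignments of the Aa and control labels within each time, drawn from 200, 4 called as many genes, the real one included, and the highest of the others called 4761. That share of the draw is under 0.05, but the 3 larger counts reversed 2 of 3 labels at 24 h relative to those at 48 h. Part of the 24 h effect was therefore added to the 48 h effect. Of all 32 assignments that parted all 3 replicate pairs at both times, not only those drawn, 5 called as many genes, the real one included. The highest other called 7686. The 4 larger counts of this set reversed 2 or 3 labels at 1 time relative to the other, and so hold the Aa effect itself. Assignments that mix Aa and control arrays keep the Aa effect in the fit. Neither share therefore decides whether chance produced the difference between the times. At 24 h 1 of the 10 splits of 6 arrays called as many genes as the real one (5492, highest other 0), at 48 h 1 of 10 (7210, highest other 0), and between control times 1 of 10 (71, highest other 1). Splits of 6 arrays are too few for a share under 0.05.

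The lists whose response differed between the times by camera had median differences of 0.526 for mitosis, 2.31 for histones, 0.248 for heat shock, -0.713 for metallothioneins, 0.649 for NF-kB and cytokines, 0.539 for immediate early genes and 0.528 for ribosome biogenesis. None of these 7 calls held with an estimated correlation, where the adjusted p was 0.0678 for histones, 0.387 for mitosis and immediate early genes, and 0.439 for the other 4 lists. That correlation was estimated without the replicate block. The mitosis median was -0.531 between the times in control cells and 0.0472 in Aa cells, where it was -0.425 with hybridisation-control scaling. Genes named for their fitted differences, which carry no order where arrays lay under log2 4, were IL11 at 5.616, TNFAIP6 at 4.951, FOSB at 4.775, ZNF143-AS1 at 4.71 and SLN at 4.58, and on the other side BLNK at -3.932, LPP at -3.337, FAM13A at -3.328, SLC40A1 at -3.3 and SLC6A3 at -3.134. Probe sets that name no single gene, which entered no comparison above, also moved with Aa: 1414 of 3213 tested changed at 24 h (889 up, 525 down) and 1867 at 48 h (1101 up, 766 down).

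Histone transcripts rose more at 48 h than at 24 h. Cross-hybridisation between near-identical histone genes does not account for it alone, because all 3 histone genes measured by plain probe sets, without the suffixes _x_at or _s_at, also rose at 48 h (3 of 3). In Aa cells the median change of DNA replication genes from 24 h to 48 h was -0.274 (bootstrap interval -0.571 to -0.148), and negative under every scaling. The histone median was 2.32 (1.11 to 3.15), so replication transcripts in Aa cells did not rise with the histones. Both intervals resample the listed genes with the arrays held fixed, so they do not measure the spread between replicates. In control cells the replication median changed by -0.386, and the difference between the log2 changes had a median of 0.127. Transcript levels do not measure the share of cells in S phase, so a larger share stays open. Polyadenylated histone transcripts may rise when cells leave the cycle or are damaged, an explanation that none of these tests addressed.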

How the results depend on the processing

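The hybridisation-control scaling was chosen after seeing the data; all other alternatives were planned. Of 151 values for named genes, 110 kept their direction and their side of the threshold under every alternative. The counts of genes changed at 24 h and 48 h stayed within 1.5 times under all alternatives except the use of every probe set, which tests more probe sets and gave 11016 at 24 h, 14369 at 48 h, 3659 for the difference between times and 8680 for calls shared between times. Leaving out single arrays gave 4816 to 5565 genes at 24 h and 6568 to 7215 at 48 h. Genes whose change differed between the times numbered 4314 with the replicate block, 650 at an adjusted p under 0.01, and 1241 (without control replicate 3 of 24 h) to 2597 (without control replicate 3 of 48 h); 1307 were called without Aa replicate 2 of 24 h, 1436 without control replicate 1 and 1259 without control replicate 2 of 48 h.

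The count between control times, 71, was 39 with equal array medians, 141 with a floor at log2 4, 146 with trend and robust eBayes, 301 with array weights, 0 with only the compared groups, 1669 with the replicate block, 6 at an adjusted p under 0.01 and 1945 with hybridisation-control scaling. It was 9 (without control replicate 1 of 24 h) to 545 (without control replicate 3 of 48 h), and every array left out moved it by over 1.5 times: 21, 22 and 18 without Aa replicates 1, 2 and 3 of 24 h, 37, 24 and 37 without those of 48 h, 14 and 12 without control replicates 2 and 3 of 24 h, and 11 and 12 without control replicates 1 and 2 of 48 h. The lower threshold explains the count at 0.01. For the others, including the compared groups with their fewer arrays, the cause was not tested. Beside the lists and counts given with the results and the call of ACTB at 48 h, the replicate block changed no other call of a named gene or list. Over all genes it called 6883 at 24 h, among them 5488 of the 5492 called without it. At 48 h it called 8193, among them 7206 of the 7210 called without it.

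Reversed values were those of ABCC3 (-0.261), CDH6 (0.0638) and SDHC (0.0169) at 24 h without probe sets ending in _x_at or _s_at, and of HSPA5 (0.297), CFLAR (0.303) and SYNPO (-0.115) at 24 h as the mean of probe sets, where the probe sets of a gene disagreed. Among genes that did not pass, GAPDH at 24 h was -0.0448 with equal array medians and -0.251 with hybridisation-control scaling, MDM2 at 24 h was -0.0667 with that scaling, and GAPDH at 48 h was 0.0316 after quantile normalisation. Leaving out single arrays gave ACTB -0.17 to 0.011 and GAPDH -0.0108 to 0.0578 at 24 h, and HMOX1 -0.207 to 0.00408 at 48 h; the cause was not tested. Calls at 24 h that were lost when single arrays were left out were those of H2BC4, HSPA5, MT1F, MT1X, LOX and PODXL. With the mean of probe sets RAD18 (0.239) and HSPA4L at 24 h and UQCRC2 at 48 h (-0.218) no longer passed, and with hybridisation-control scaling DNAJB9, BAG3 and NOP58 at 24 h and CYCS at 48 h (0.292) no longer passed. For the difference between times LPP lost its call without Aa replicates 2 and 3 of 24 h, Aa replicate 3 of 48 h, any control replicate of 24 h, and control replicates 1 and 2 of 48 h (-3.43 to -3.2). FAM13A lost its call without Aa replicates 1 and 2 of 24 h, Aa replicates 2 and 3 of 48 h, control replicate 3 of 24 h, and control replicates 1 and 2 of 48 h (-3.26 to -2.73). Between control times SLC6A13 at 1.95, CDON at 1.75 and TM4SF4 at -2.28 lost their calls without most single arrays, KLF7 at -1.45 without control replicate 1 of 48 h, and all 10 named genes with only the compared groups. With no expression filter, camera at the preset correlation also called the p53, DNA replication, DNA repair and immediate early lists at 24 h. An estimated correlation was tried only with the filter, where camera gave these lists adjusted p from 0.556 to 0.815. Signal near background limits calls of dim genes, as the floor shows for COL4A3 (0.815) and KISS1R (0.762) between control times.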

Other observations

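The symbol families, transcript classes, span classes and the set of genes near background were chosen after the data were seen. All 3 tests for the genes near background, and the bound that defined them, were also chosen only after the result was seen. Among 72 symbol families with at least 15 tested members, zinc finger genes with ZNF symbols rose at 24 h in 163 of 360 cases and fell in 23 (median 0.38, camera adjusted p = 4.86e-05; adjusted p = 0.904 with an estimated correlation), against 104 and 52 with hybridisation-control scaling (median 0.09). At 48 h 158 rose and 64 fell (median 0.24, camera adjusted p = 0.0176; adjusted p = 0.926 with an estimated correlation), and with that scaling 103 rose and 138 fell (median -0.20). Of 17 genes of intraflagellar transport with IFT symbols, which build cilia, 12 fell at 24 h (median -0.72, camera adjusted p = 0.013; adjusted p = 0.904 with an estimated correlation), as did 12 with that scaling. At 48 h 11 fell and 1 rose, and the family did not pass camera (median -0.83, adjusted p = 0.0735). RNA helicase genes with DDX symbols rose in 15 of 32 cases and fell in 2 at 24 h (median 0.30, camera adjusted p = 0.0435), against 9 and 4 with hybridisation-control scaling (median 0.02). At 48 h 19 rose and 4 fell (median 0.75, camera adjusted p = 0.0176), against 13 and 10 with that scaling (median 0.31). With an estimated correlation the DDX family had adjusted p = 0.904 at 24 h and adjusted p = 0.926 at 48 h. Sorting nexin genes with SNX symbols fell in 15 of 26 cases at 48 h (median -0.44, camera adjusted p = 0.0222; adjusted p = 0.926 with an estimated correlation), and in 23 with that scaling (median -0.88). At 24 h 4 rose and 8 fell, and the family did not pass camera (adjusted p = 0.477). Transcribed pseudogenes rose in 51 of 126 cases and fell in 10 at 24 h (median 0.23), against 43 and 19 with hybridisation-control scaling (median -0.05), and rose in 64 and fell in 12 at 48 h (median 0.49), against 41 and 37 with that scaling (median 0.05).

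Genes that span more of the genome fell more with Aa. Across 11176 genes with a span, the rank correlation of span with log2 change was -0.247 at 24 h (95% bootstrap interval -0.265 to -0.226) and -0.366 at 48 h (-0.383 to -0.349). These intervals resample genes with the arrays held fixed, so they do not measure the spread between replicates. Single Aa arrays against the mean of their controls gave -0.273, -0.171 and -0.279 at 24 h. At 48 h they gave -0.359, -0.322 and -0.397. Of 708 genes spanning at least 200 kb, 527 fell and 23 rose at 24 h, and 611 fell and 20 rose at 48 h, with 516 fallen at both times. Their median log2 change was -1.41 and -1.90, and -1.69 and -2.34 with hybridisation-control scaling. Genes under 10 kb fell in 18.1% of cases at 24 h and 22.9% at 48 h. Several genes named for their falls were long, among them GPHN (1230 kb), DIAPH2 (920 kb), EXOC4 (848 kb), PTPRG (736 kb), ANK3 (707 kb) and SYT1 (588 kb), while GPR160 spanned 47.4 kb.

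Baseline brightness does not account for the span pattern, since the median correlation within classes of control level was -0.237 at 24 h. With each gene's second probe set the correlation was -0.3 over 5506 genes (interval over resampled genes -0.326 to -0.274), so the choice of probe set does not account for it. Aa and control cells were compared at the same time, so time in culture does not account for it either. Between control times the correlation was 0.153, so the change in control cells can add to the negative correlation at 48 h. RNA quality stays open: the 3' minus 5' difference of the ACTB and GAPDH control probe sets was higher on Aa arrays by 0.156 (0.0883 at 24 h and 0.223 at 48 h), against an SD of 0.0688 on control arrays. Within each time the Aa arrays with a higher ACTB difference had the weaker span correlation, against what RNA quality would give. At 24 h 0.618, 0.833 and 1.24 went with -0.279, -0.273 and -0.171. At 48 h 0.944, 1.04 and 1.46 went with -0.397, -0.359 and -0.322. Control arrays held the same ACTB order by replicate number. Their replicate 2 was highest (0.857 at 24 h, 0.979 at 48 h) and replicate 3 lowest (0.68 and 0.5825). For GAPDH the order at 24 h was the reverse, as RNA quality would give. There -0.0895, -0.0901 and -0.149 went with -0.279, -0.273 and -0.171. At 48 h the GAPDH difference followed neither order. With 3 arrays per time these orders cannot decide. Aa replicate 3 at 24 h, with 0.618, lay below control replicate 3 (0.68). A block of transcript elongation, by which long genes would lose more transcript, is a candidate explanation that was not tested directly.

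Some genes near background in control cells rose with Aa. Of 19775 genes, 8691 lay under log2 4 on all 6 control arrays and 8574 on all 6 Aa arrays; by limma 13 of the former were at least 16-fold higher with Aa at 24 h and 19 at 48 h (9 at both), and 5 and 7 of the latter were at least 16-fold lower, with dim values entered at log2 4. Of the 8691 genes, 94.3% lay under log2 4 on all 6 Aa arrays too, so most genes of like level did not rise over log2 4. The normalisation sets the arrays to nearly the same distribution, so scaling could hardly have lowered this share. The share therefore does not decide whether scaling between arrays, which moves genes of like level together, added to the rises. Cells of another listed type do not account for the rises, since at most 9.09% of the markers of any of the 4 lists on the array rose at 48 h. The behaviour of single probe sets stays open: only 8 of the 19 genes had a further probe set, which rose as well in 62.5% of them (exact binomial interval 24.5 to 91.5), against 22.4% of all 7490 tested genes with a further probe set.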
